A study of Mus musculus with 4 samples.

How the data were processed

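RNA-seq counts from mouse liver were analysed in 4 libraries, 2 of the group labelled ND and 2 of the group labelled HFD. Per the labels' protocols, RNA was extracted with Trizol, messenger RNA was enriched on oligo(dT) beads, fragmented and copied to complementary DNA, and the libraries were sequenced as DNA nanoballs. The protocol does not say whether the libraries keep the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. The authors deposited 1 table of counts per gene symbol and library. Its values are whole numbers that are not scaled to a common total. Per the submitters' processing notes, Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and the genome build mm10 were used, without roles or order. Which of these made the table, the annotation and the treatment of reads that match several genes are not given in the sources used here. Since RSEM estimates counts, the deposited whole numbers could be rounded estimates. The table also holds columns of fold changes, tests and sums made by the submitters, which were not used here.

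The columns of the HFD libraries carry the names of the labels. The columns of the other group are headed chow with the same replicate numbers, and were taken as the ND libraries because ND is the only other group of the labels. This mapping is an inference from the names. The replicates of a group differed by more than sampling noise (chi-square per degree of freedom 27.5 in ND and 11.5 in HFD). This compares them with counting noise only and cannot tell whether they came from separate animals. Each library was counted as its own sample. The Spearman correlation across genes was 0.975 between the ND libraries and 0.985 between the HFD libraries, and 85 and 12 genes differed by over 4-fold.

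Of 35976 rows, 19768 had a count. Spreadsheet software had turned 27 gene names into dates, and 4 rows had repeated names. These rows stayed in the totals and the tests and are not named. Library totals ran from 8600710 to 9466396 counts. At this depth a gene at 1 CPM had about 9 counts per library, and intervals given from counts cover counting error only.

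Before the data were examined, the design, the gene lists, the alternatives and the rule for named genes were fixed. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum of 10 counts, which left 12544. TMM factors, a dispersion trend, glmQLFit and glmQLFTest with default settings followed, with the group as the only term. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Fold changes are fitted with a prior count of 0.125. Adjusted p-values are Benjamini-Hochberg over all tested genes with a threshold of 0.05. Levels are CPM scaled by the TMM factors.

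Of 40 lists of genes, 24 were pathways or gene groups of the liver and 16 were markers of cell types a liver piece could hold. The 35 with at least 5 tested members were tested with camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. As counted, 7 lists were higher and 3 lower. With an estimated correlation none of these calls held (lowest adjusted p = 0.580), nor with fry, which tests whether the genes of a list move on balance one way (lowest adjusted p = 0.0803). At 2 libraries per group an estimated correlation rests on few residual degrees of freedom. That test has little power here, so its adjusted p decides neither for nor against a list. The lists overlap in some genes, and together hold 576 different tested genes.

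Named genes were, for each direction, the 12 with the largest fold change among genes past the threshold with a mean of at least 5 CPM, with both HFD libraries on the same side of both ND libraries and with no predicted-gene name. Zrsr1, Zrsr2, Nr1h3, Srebf1, Fasn and Scd1 were added whatever their values, as were from each list up to 4 members with the smallest p, or 2 with the highest level where none passed. Of the genes this rule chose, 2 were left out and not replaced. The other 141 were followed through the alternatives, but not all of them are described, and which ones are was decided after their values were seen. Other genes are named only as list members that go against their list or were chosen after their values were seen. These exceptions are Cyp7a1, Abca1, Abhd5, Herpud1, Saa1, Saa2, Hao2, Elovl3, and the genes of the closing observations. Gene positions were taken from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, by gene symbol.

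The alternatives were DESeq2 1.42.0 size factors, upper quartile factors, no filter on low counts beyond 1 count, a stricter filter of 5 CPM in 2 libraries, DESeq2 1.42.0 as the test, limma 3.58.1 with trend on log2 CPM with a prior count of 2, a threshold of 2-fold, a test against a fold change of 1.2, the replicate number as a block, and each library left out in turn. Where a library was left out, the lone library of its group was assumed to vary like the other group. The planned legacy quasi-likelihood method is the installed default of this edgeR version and was not run separately.

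Chosen after seeing the data were the newer quasi-likelihood method, the length and GC correction, that correction without ND replicate 2, the scan of gene families and the split of the sex-biased list. For the correction, the length and GC content of the longest annotated transcript were used, known for 94.5% of tested and 95.2% of changed genes. Mitochondrially encoded genes, whose names did not match, were left uncorrected. In each library a spline with 4 degrees of freedom on log2 length and on GC content was fitted to the log2 deviations and entered as an offset. Since the trend separates the groups, the correction also removes any difference between the diets that follows GC content or length.

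The procedure was tested on simulated data, with 12544 genes drawn from the means, dispersions and totals of these libraries and 200 genes changed between HFD and ND. Of the changed genes 74.0% were recovered at a log2 fold change of 1 and 100% at 2, and 7.94% of the calls were unchanged genes. With the GC slopes of the real libraries added, 78.4% of the calls were unchanged genes without the correction and 5.08% with it, when 69.0% and 99.0% of the changed genes were recovered. These shares rest on the 200 genes chosen to change, while 3675 genes were called in the real data, so they do not carry over. The added trend was unrelated to which genes were changed. How the correction acts where diet differences follow GC content was not simulated. In a simulation of the list test, a list shifted by 0.7 on the log2 scale passed and 0 of 20 unshifted lists did. Genes were drawn independently of each other there, so false calls from members that move together could not appear.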

Results

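Liver RNA from mice was profiled in 4 libraries of polyadenylated RNA, 2 from a group the labels call ND and 2 from a group called HFD. HFD is the usual abbreviation of a high-fat diet, and the series' design text gives 13 weeks of HFD feeding for mice with hepatic overexpression of Zrsr1 and their controls. The file heads the ND columns as chow, a standard rodent diet, and all 4 library names carry the prefix GFP. The series title concerns Zrsr1, a splicing factor gene, the lipid-synthesis axis of the nuclear receptor LXR and the transcription factor SREBP1c, and the splicing of minor introns. The 4 libraries analysed here allow 1 comparison, HFD against ND. Total counts were 9054917 in ND replicate 1, 8698496 in ND replicate 2, 9466396 in HFD replicate 1 and 8600710 in HFD replicate 2. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries. Levels are normalised read counts scaled to library size (CPM) as mean ± SD (n = 2), fold changes are HFD relative to ND, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. Positions are those of mm10, and all genes given with a position are protein-coding.

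The comparison asked which liver transcripts differed with diet. Lists of fatty acid oxidation, lipid droplet and lipogenesis genes were higher in HFD and the unfolded protein response was lower with camera at a fixed correlation. These list calls were lost with an estimated correlation (adjusted p = 0.580 for the 3 lipid lists and 0.751 for the unfolded protein response) and with fry. The fry adjusted p was 0.0803 for fatty acid oxidation and for lipid droplets, 0.0997 for lipogenesis and 0.138 for the unfolded protein response. The estimated correlation has little power at 2 libraries per group, so its losses cannot tell whether the lists differed. Of 12544 genes tested, 1402 were higher and 2273 lower in HFD at an adjusted p under 0.05, and 523 and 1474 of these differed by at least 2-fold. The first principal component of the log2 CPM values held 77.3% of the variance and separated the groups, while the second held 13.7% and separated the 2 ND libraries. Without HFD replicate 2 the counts were 417 higher and 1132 lower. Transcript GC content and length differed in their relation to expression between the groups, and with a correction for both, chosen after seeing the data, 1232 genes were higher and 930 lower.

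Among the 12 largest rises were several genes of fatty acid and lipid metabolism. Cyp4a14, a fatty acid omega-hydroxylase (chromosome 4, 115486200 to 115496142), rose from 6.88 ± 8.43 to 738 ± 69.9 CPM, a log2 fold change of 6.73 ± 0.81 (SE, adjusted p = 0.00096). Without ND replicate 1, where most of its ND counts lay, the log2 fold change was 9.62. The related Cyp4a10 rose by a log2 fold change of 3.93 ± 0.63 and the acyl-CoA thioesterase genes Acot3 and Acot2 by 4.94 ± 0.57 and 3.85 ± 0.34. G0s2, an inhibitor of the triglyceride lipase ATGL (chromosome 1, 193272161 to 193273217), rose 13.1-fold from 21.6 ± 4.73 to 282 ± 28.7 CPM. Fgf21, a fasting and stress hormone of the liver, rose 12.7-fold from 0.962 ± 0.436 to 12.3 ± 1.08 CPM, and the apolipoprotein gene Apoa4 rose 11.8-fold to 1421 ± 464 CPM. Cfd, which encodes complement factor D (log2 fold change 4.69 ± 0.49), the hepcidin gene Hamp2 (3.94 ± 0.41), the cell cycle inhibitor Cdkn1a (3.58 ± 0.50) and the class I histocompatibility gene H2-Q1 (3.44 ± 0.22) also rose. Without ND replicate 1 the log2 fold change was 7.29 for Acot3, 6.52 for Cfd, 5.01 for Hamp2, 5.57 for Cyp4a10 and 4.50 for Acot2. Without ND replicate 2 it was 5.85 for Cyp4a14, 4.12 for Acot3, 3.93 for Cfd, 3.34 for Hamp2 and 3.19 for Cyp4a10. That of Cdkn1a was 4.18 without HFD replicate 1 and 2.62 without HFD replicate 2. Cyp2b9, a cytochrome P450 (chromosome 7, 26173411 to 26210661), had 1 count in the ND libraries together and 1429 in the HFD libraries, a ratio of 1404 with a 95% counting interval from 252 to 55501. Its fitted log2 fold change of 10.15 was 9.35 without ND replicate 2 and 8.20 with limma, and no ND count was left without ND replicate 1. That of Cyp4a14 was 7.57 with limma. Reads of the Cyp4a, Acot, Hamp and H2-Q copies could be exchanged between near-identical genes, so the values of single copies are uncertain.

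Among the 12 largest falls were 5 major urinary protein genes, which encode pheromone carriers made by the liver. Mup17 fell 17.3-fold from 2592 ± 937 to 150 ± 65.8 CPM and Mup15 fell 18.6-fold from 2433 ± 1508 to 131 ± 33.9 CPM. Mup6, Mup9 and Mup18 had log2 fold changes of -6.56 ± 1.15, -4.57 ± 0.49 and -4.09 ± 0.52. The glucuronosyltransferase genes Ugt2b37 and Ugt2b38 (-5.01 ± 0.78 and -3.96 ± 0.38), Cyp2c40 (-4.73 ± 0.41) and the selenium-binding protein gene Selenbp2 (-3.90 ± 0.23) fell as well. These genes belong to families of near-identical copies that can share reads, so the values of single copies are uncertain. Gadd45g, a stress-response gene (chromosome 13, 51846678 to 51848468), fell 15.2-fold from 108 ± 24.6 to 7.17 ± 3.81 CPM. Moxd1, a monooxygenase-like gene, had 1747 counts in the ND libraries and 1 in the HFD libraries, a ratio of 1778 for ND over HFD (95% counting interval 319 to 70262). Its level was 3.81 CPM in ND replicate 1 and 198 CPM in ND replicate 2, and without ND replicate 2 the log2 fold change of Moxd1 was -5.78. Without that library the values were -3.67 for Mup6, -3.57 for Mup9, -3.38 for Mup15, -2.88 for Mup18, -3.63 for Ugt2b37 and -3.29 for Ugt2b38. Without ND replicate 1 they were -7.46 for Mup6, -4.74 for Mup18, -5.71 for Ugt2b37 and -11.47 for Moxd1. Cyp2c40 measured -4.14 and -5.57 without HFD replicates 1 and 2, and without HFD replicate 2 Moxd1 measured -9.72 and Gadd45g -4.59. Without HFD replicate 1 no HFD count of Moxd1 was left. With limma the values were -6.70 for Moxd1, -5.39 for Mup6 and -4.24 for Ugt2b37, against -10.49 for Moxd1 in the edgeR fit. The length and GC correction gave -5.87 for Mup6, -3.97 for Mup9, -4.21 for Ugt2b37 and -3.16 for Ugt2b38. The immediate early gene Fos, also among the 12, is described with its list.

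The list of LXR and SREBP1c lipogenesis genes was higher in HFD. Of its 28 members, all tested, 17 rose, 2 fell and 9 did not pass, and 19 were higher and 3 lower when adjusted over the list alone. The median log2 fold change was 1.04, with a camera adjusted p of 5.43e-09 and an adjusted p = 0.580 with an estimated correlation. Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids (chromosome 19, 44394455 to 44407879), rose 4.46-fold from 3349 ± 832 to 14929 ± 2442 CPM (adjusted p = 0.000773). Elovl5, an elongase of polyunsaturated fatty acids (chromosome 9, 77917364 to 77984519), rose 8.42-fold to 1090 ± 50.6 CPM, and the desaturase genes Fads2 and Fads1 rose 4.05-fold and 3.13-fold. Pltp, which encodes the phospholipid transfer protein, rose 4.12-fold. The members that fell were Abca1, a cholesterol exporter (log2 fold change -1.42 ± 0.20), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-1.19 ± 0.27). Cyp7a1 no longer passed with the length and GC correction (-0.27, adjusted p = 0.530).

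Neither Nr1h3 nor Srebf1, the genes at the head of this axis, passed when adjusted over all genes, nor did the lipid synthesis gene Fasn. Adjusted over the list alone, Nr1h3 and Fasn passed (adjusted p = 0.0460 and 0.0216) and Srebf1 did not (0.265). Srebf1, the gene of SREBP1 (chromosome 11, 60199089 to 60222581), measured 192 ± 35.9 CPM in ND and 226 ± 12.4 CPM in HFD, a log2 fold change of 0.23 ± 0.19 (adjusted p = 0.374). Over the alternatives the log2 fold change of Srebf1 ran from 0.02 to 0.44. Nr1h3, which encodes LXR-alpha (chromosome 2, 91184061 to 91202834), had a log2 fold change of 0.43 ± 0.17 (adjusted p = 0.0937), and of 0.09 (adjusted p = 0.697) with the length and GC correction. Fasn, the fatty acid synthase gene (chromosome 11, 120805846 to 120824547), measured 440 CPM on average in ND and 799 ± 379 CPM in HFD, a log2 fold change of 0.86 ± 0.29 (adjusted p = 0.0518). Its HFD libraries differed, at 1067 and 531 CPM, and it passed the threshold under 9 of the alternative settings. It did not pass with the length and GC correction (adjusted p = 0.0885), limma (0.0725), the newer quasi-likelihood method (0.0511) or without HFD replicate 1 (0.401), where its log2 fold change was 0.29. Zrsr1 (chromosome 11, 22972005 to 22976496) measured 18.0 ± 0.439 CPM in ND and 13.5 ± 0.175 CPM in HFD, a log2 fold change of -0.41 ± 0.18 (adjusted p = 0.118). Over the alternatives the log2 fold change of Zrsr1 ran from -0.43 to -0.06. Zrsr2, its X-linked relative and a protein of the minor spliceosome (163935443 to 163958661 on chromosome X), had a log2 fold change of -0.47 ± 0.30 (adjusted p = 0.259), which was 0.20 with the length and GC correction.

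**Figure D1:**
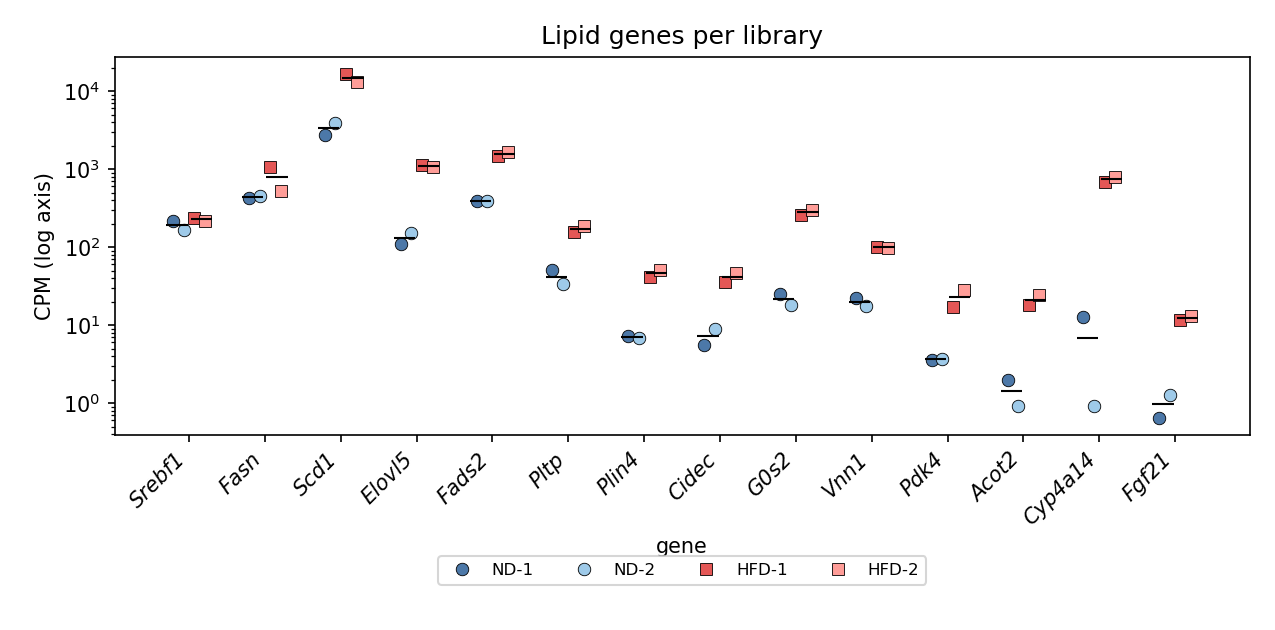
Normalised read counts (CPM, log axis) of 14 genes of lipid metabolism in each library, with circles for ND, squares for HFD and a black line at each group's mean. Elovl5 lay at 109 and 150 CPM in ND and at 1126 and 1054 CPM in HFD, while Srebf1 lay at 218 and 167 against 235 and 217 CPM.

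Genes of fatty acid oxidation and ketogenesis controlled by the nuclear receptor PPARA rose together. Of 26 tested members 22 rose and none fell, and 24 were higher when adjusted over the list alone. The median log2 fold change was 1.06, with a camera adjusted p of 1.60e-16 and an adjusted p = 0.580 with an estimated correlation. Vnn1, a pantetheinase gene (chromosome 10, 23894688 to 23905343), rose 5.01-fold from 19.8 ± 3.06 to 99.4 ± 3.42 CPM, and Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose 6.20-fold from 3.64 ± 0.0728 to 22.7 ± 7.72 CPM. Acot2 and Fgf21, given above, are members too.

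The list of lipid droplet genes and PPARG targets was also higher, with 14 of 21 tested members risen and 2 fallen, and 15 and 2 when adjusted over the list alone. Its median log2 fold change was 1.08 (camera adjusted p = 5.88e-11, adjusted p = 0.580 with an estimated correlation). Plin4, a perilipin that coats lipid droplets (chromosome 17, 56100591 to 56109803), rose 6.48-fold from 7.11 ± 0.258 to 46.2 ± 6.26 CPM. Cidec, which promotes the fusion of lipid droplets, rose 5.68-fold from 7.28 ± 2.44 to 41.3 ± 7.34 CPM. The members that fell were Lpl, the lipoprotein lipase gene (log2 fold change -1.34 ± 0.25), and Abhd5, the gene of a lipase co-activator (-0.74, adjusted p = 0.0415). With the length and GC correction neither passed, at -0.73 (adjusted p = 0.0800) for Lpl and -0.43 (adjusted p = 0.192) for Abhd5. Secreted and membrane factors associated with steatosis had 10 of 15 tested members risen and none fallen, 11 and none when adjusted over the list alone, with a median log2 fold change of 1.07 (camera adjusted p = 2.90e-09, adjusted p = 0.580 with an estimated correlation). Gpc1, a glypican gene, rose 6.24-fold and Lgals1, the galectin-1 gene, rose 5.81-fold, while Anxa5, an annexin gene, rose 1.91-fold. After the length and GC correction 6 members of this list were higher.

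Apolipoprotein and lipoprotein handling genes had 8 of 20 tested members risen and 4 fallen, 10 and 4 when adjusted over the list alone, with a median log2 fold change of 0.44 (camera adjusted p = 0.0312, adjusted p = 0.580 with an estimated correlation). With the length and GC correction the median was 0.21 and the adjusted p 0.154, with 5 members higher and 3 lower. With that correction without ND replicate 2 the median was 0.20 and the adjusted p 0.0557. Besides Apoa4, Apoc1 rose 2.06-fold and Tm6sf2, a gene that affects hepatic lipoprotein secretion, rose 2.16-fold. Sort1, the sortilin gene, fell 2.07-fold. Subunits of the mitochondrial respiratory chain encoded in the nucleus had 10 of 24 tested members risen and 1 fallen, 14 and 1 when adjusted over the list alone. The median log2 fold change was 0.51 (camera adjusted p = 0.0104, adjusted p = 0.785 with an estimated correlation and 0.138 with fry). After the length and GC correction 5 members were higher and none lower, with a median of 0.33. Cox6c, a subunit of cytochrome c oxidase, rose by a log2 fold change of 0.72 ± 0.17, which without HFD replicate 1 was 0.62 with an adjusted p of 0.0785. None of the 13 mitochondrially encoded transcripts passed (edgeR adjusted over all genes or over the list alone), with a median log2 fold change of 0.12 (camera adjusted p = 0.480). The level of COX1 was high in all libraries, with a log2 fold change of -0.15 ± 0.20, and that of CYTB was 0.11 ± 0.20.

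Other metabolic lists held genes that moved in both directions and did not pass the list test. In cholesterol synthesis 1 of 24 tested members rose and 4 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.624). Idi1, the isopentenyl diphosphate isomerase gene, fell 5.96-fold from 97.4 ± 8.66 to 16.3 ± 2.98 CPM, and the sterol carrier gene Stard4 fell 3.85-fold, while Pmvk, the phosphomevalonate kinase gene, rose 2.28-fold. The length and GC correction gave log2 fold changes of -1.91 for Idi1 and -1.34 for Stard4, against -2.58 and -1.94 as counted, and 2 members higher and 3 lower. In bile acid synthesis and transport 5 of 20 rose and 5 fell, 6 and 5 when adjusted over the list alone (camera adjusted p = 0.608). Cyp7b1, an oxysterol hydroxylase of the alternative pathway (chromosome 3, 18071950 to 18243338), fell 7.51-fold from 449 ± 96.3 to 59.7 ± 7.81 CPM, and Cyp2c70, which makes muricholic acids, fell 4.71-fold. The organic anion transporter genes Slco1a1 and Slco1b2 fell 6.38-fold and 3.12-fold, with log2 fold changes of -2.67 and -1.64 as counted and -1.68 and -0.69 after the length and GC correction. The median, the mean and the test of these 2 lists differed in sign, with medians of 0.07 and 0.02 and means of -0.23 and -0.18. In glycolysis and gluconeogenesis 9 of 24 rose and 1 fell, 11 and 1 when adjusted over the list alone (median 0.39, camera adjusted p = 0.0528). The gluconeogenic genes Fbp1 and Pcx rose 1.94-fold and 1.95-fold. Pfkfb3, which makes the activator of phosphofructokinase, fell 4.95-fold.

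In xenobiotic metabolism 4 of 24 tested members rose and 9 fell, 4 and 10 when adjusted over the list alone (median -0.30, camera adjusted p = 0.658). Cyp3a11, the main drug-metabolising enzyme gene of its subfamily, fell 4.95-fold from 1750 ± 539 to 354 ± 74.3 CPM, Cyp1a2 fell 3.18-fold from 1011 ± 48.5 to 318 ± 19.7 CPM and Ugt2b1 fell 4.68-fold. The log2 fold changes of Cyp3a11 and Ugt2b1 were -2.31 and -2.23 as counted and -1.53 and -1.45 after the length and GC correction, which left 2 members higher and 6 lower. The antioxidant targets of NRF2 had 6 of 14 risen and 1 fallen, with the same counts when adjusted over the list alone (median 0.21, camera adjusted p = 0.0548). That list had an adjusted p of 0.0357 with the length and GC correction at the fixed correlation of 0.01, and an adjusted p of 0.580 as counted with an estimated correlation. Nqo1, a quinone reductase, rose 2.24-fold and Tkt, a transketolase of the pentose phosphate pathway, rose 1.73-fold, and without HFD replicate 2 their adjusted p-values were 0.0635 and 0.0563. Of 17 circadian clock genes 4 rose and 3 fell, also when adjusted over the list alone (median -0.09, mean -0.05, a test direction upwards, camera adjusted p = 0.844). Arntl, a core activator of the clock, rose 3.50-fold, and Nr1d2, a repressor, fell 2.94-fold. The log2 fold change of Nr1d2 was -1.56 as counted and -0.77 after the length and GC correction, which left 3 members higher and 2 lower. Clock fell by 1.11 on the log2 scale and measured -0.02 with the length and GC correction (adjusted p = 0.965).

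Genes of the unfolded protein response were lower in HFD. Of 20 tested members 12 fell and 1, Herpud1, rose, and 14 were lower and 2 higher when adjusted over the list alone. Herpud1 did not pass with the length and GC correction (log2 fold change 0.57, adjusted p = 0.141). The median log2 fold change of the list was -1.03, with a camera adjusted p of 7.96e-06 and an adjusted p = 0.751 with an estimated correlation. Hsp90b1, the endoplasmic chaperone GRP94 (chromosome 10, 86690209 to 86705509), fell 5.02-fold from 1006 ± 92.9 to 200 ± 0.0205 CPM. Creld2 (chromosome 15, 88819646 to 88826683) fell 6.15-fold to 28.5 ± 5.93 CPM, and the co-chaperone genes Dnajc3 and Sdf2l1 fell 3.41-fold and 3.19-fold. The log2 fold changes of Hsp90b1 and Dnajc3 were -2.33 and -1.77 as counted and -1.66 and -1.08 after the length and GC correction. In the list of cytosolic heat shock proteins 6 of 14 tested members fell and none rose, also when adjusted over the list alone (median -0.19, camera adjusted p = 0.0964). The name does not hold for Hspd1, 1 of the 6, which encodes a chaperonin of the mitochondrial matrix (log2 fold change -0.74 ± 0.17, adjusted p = 0.104 without HFD replicate 2). Hsp90aa1 fell 5.44-fold from 211 ± 28.3 to 38.9 ± 10.1 CPM. Dnaja1 fell 2.40-fold, but with the length and GC correction its log2 fold change was -0.37 (adjusted p = 0.178), and 3 members of the list were lower and 1 higher.

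Of 15 tested minor spliceosome proteins 5 fell and none rose, also when adjusted over the list alone (median -0.41, camera adjusted p = 0.201). Sf3b1 and Dhx15, which serve both spliceosomes, fell 2.78-fold and 2.21-fold. Their log2 fold changes were -1.47 and -1.14 as counted and -0.62 and -0.60 after the length and GC correction. Rnpc3, a protein specific to the minor spliceosome, had a log2 fold change of -1.08 ± 0.26 (adjusted p = 0.0154), which was -0.80 without HFD replicate 1 (adjusted p = 0.0809) and 0.30 with the length and GC correction. The members of this list had a median GC content of 46.8%, against 49.8% for all tested genes, and with the correction the median was -0.06 and 3 members were lower. Of 28 cytosolic ribosomal proteins 6 fell and none rose, 5 and none when adjusted over the list alone. Their median was 0.04, their mean -0.12 and the test direction downwards (camera adjusted p = 0.729), and with the length and GC correction the list had a median of -0.24, 4 members lower and an adjusted p of 0.0230. As counted with an estimated correlation its adjusted p was 0.858. Rpl7 had a log2 fold change of -0.91 ± 0.17.

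Acute phase genes, which the liver secretes in inflammation, were lower in HFD, and their level also differed between the ND libraries. Of 22 tested members 9 fell and none rose, and 13 fell when adjusted over the list alone. The median log2 fold change was -1.28, with a camera adjusted p of 0.00174 and an adjusted p = 0.785 with an estimated correlation. With fry the adjusted p of the list was 0.433. Without ND replicate 2 the median was -0.20 and the camera adjusted p 0.106, while the length and GC correction without that library gave a median of -0.31 and a camera adjusted p of 0.00441 at the fixed correlation. Hamp, the hepcidin gene (chromosome 7, 30942368 to 30944032), fell 2.50-fold from 1193 ± 193 to 478 ± 17.1 CPM, and the fibrinogen genes Fgg and Fgb fell 2.72-fold and 2.74-fold. These and Orm1, which fell 2.36-fold, lay lower in both HFD libraries than in either ND library. Saa1 and Saa2, chosen after their values were seen, measured 236 and 118 CPM in ND replicate 1, 1248 and 1359 CPM in ND replicate 2, and between 35.9 and 106 CPM in HFD. They are near-identical copies that can share reads.

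Immediate early and glucocorticoid response genes had 4 of 20 tested members fallen and none risen, also when adjusted over the list alone (median -1.16, camera adjusted p = 0.0964). With the length and GC correction the list had an adjusted p of 0.000403 at the fixed correlation of 0.01. As counted, its adjusted p was 0.785 with an estimated correlation and 0.456 with fry. The median log2 ratio of ND replicate 2 to ND replicate 1 was 1.54 for this list and 0.91 for the acute phase list. Fos measured 4.35 CPM in ND replicate 1 and 325 CPM in ND replicate 2, against 1.49 and 3.99 CPM in HFD, and Egr1 measured 19.4 and 609 against 16.4 and 28.1 CPM. Their log2 fold changes were -5.92 ± 1.54 and -3.82 ± 1.15, and without ND replicate 2 they were -0.68 (adjusted p = 0.254) and 0.20 (adjusted p = 0.624). Neither Fos nor Egr1 passed without HFD replicate 1 (adjusted p = 0.0680 and 0.107) or HFD replicate 2 (adjusted p = 0.0753 and 0.111), and Egr1 did not pass with the length and GC correction (adjusted p = 0.0562). On all 4 libraries limma gave log2 fold changes of -3.84 for Fos and -2.33 for Egr1 that did not pass (adjusted p = 0.0892 and 0.176), nor did Egr1 with DESeq2 (adjusted p = 0.116). Without ND replicate 1 the values were -6.91 for Fos and -4.78 for Egr1, and with the replicate number as a block they were -5.01 for Fos and -2.45 for Egr1. Dusp1, a MAP kinase phosphatase gene, had a log2 fold change of -1.15 ± 0.18 with similar ND libraries (87.7 and 99.8 CPM). Of 14 chemokine and cytokine genes 3 fell and none rose, also when adjusted over the list alone (median -1.24, camera adjusted p = 0.0964). Il1b, an inflammatory cytokine gene, fell 5.19-fold to 1.90 ± 0.131 CPM. Cxcl1 measured 567 CPM in ND replicate 2 and between 5.22 and 9.39 CPM in the other 3 libraries, and without ND replicate 2 its log2 fold change was -0.18 (adjusted p = 0.723). Cxcl1 did not pass without HFD replicate 1 (adjusted p = 0.0764), without HFD replicate 2 (0.0923) or with the length and GC correction (0.0584), where 1 member of the list was higher and 1 lower. Its log2 fold change of -5.30 was -3.26 with limma (adjusted p = 0.127), -3.67 with the replicate number as a block and -6.29 without ND replicate 1. Of 25 interferon-stimulated genes 2 rose and 3 fell, also when adjusted over the list alone (median -0.22, camera adjusted p = 0.537), among them Ifit1 and Mx2 with log2 fold changes of -2.19 ± 0.38 and -2.08 ± 0.37. After the length and GC correction none of these genes was higher and 3 were lower.

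**Figure D2:**
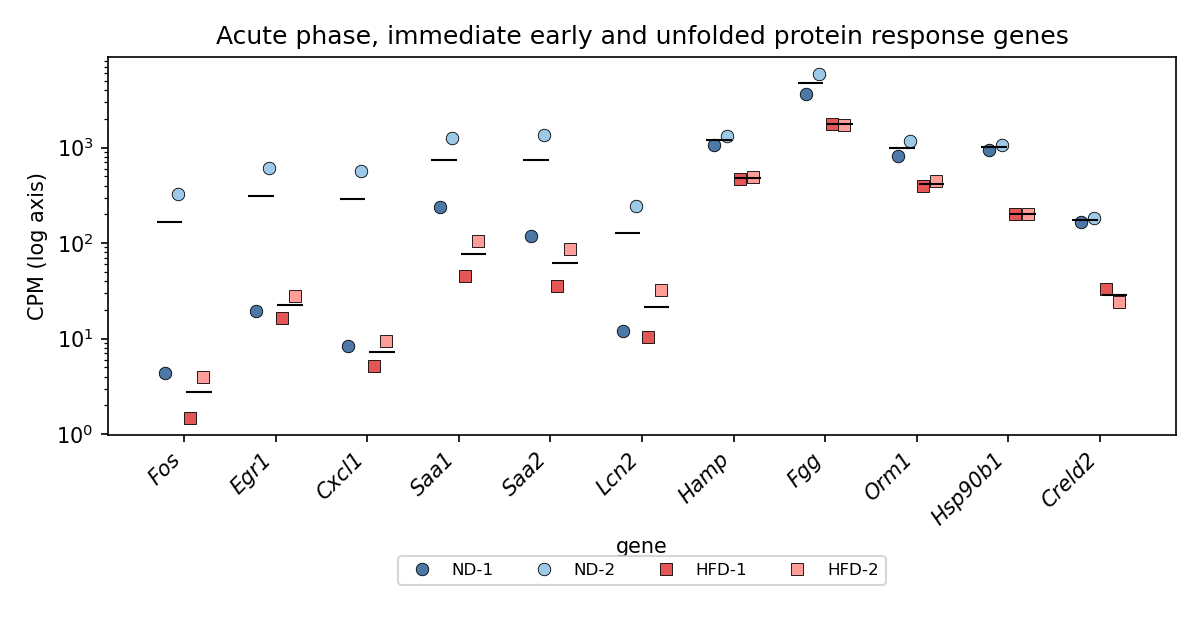
Normalised read counts (CPM, log axis) of 11 genes of the acute phase, immediate early, chemokine and unfolded protein response lists in each library, with circles for ND, squares for HFD and a black line at each group's mean. Fos stood at 325 CPM in ND replicate 2 and at 4.35 CPM in ND replicate 1, whereas Hsp90b1 had similar levels within each group, with SDs of 92.9 and 0.0205 CPM.

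Liver genes that differ between the sexes were mostly lower in HFD, with 13 of 18 tested members fallen and 3 risen, also when adjusted over the list alone. The other 8 of the 26 members, all female-biased, had too few counts to be tested. The median log2 fold change was -1.53, with a camera adjusted p of 7.87e-05 and an adjusted p = 0.580 with an estimated correlation. Serpina1e, an antitrypsin gene (chromosome 12, 103946931 to 103958975), fell 9.13-fold from 15313 ± 3585 to 1677 ± 206 CPM and Mup1 fell 6.96-fold from 605 ± 113 to 87.0 ± 16.8 CPM, although reads of their near-identical copies could be exchanged. The members that rose were Cyp2b9, Elovl3, a fatty acid elongase gene (2.26 ± 0.21), and Hao2, a hydroxyacid oxidase gene with no count in ND and 31 counts in HFD. The level of Hao2 was at least 10.3-fold higher in HFD, with the ND libraries together set at 3 counts.

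Fibrosis and extracellular matrix genes had 6 of 18 tested members risen and none fallen, also when adjusted over the list alone. The median log2 fold change was 0.52 (camera adjusted p = 0.0222, adjusted p = 0.751 with an estimated correlation and 0.289 with fry). The camera adjusted p was 0.201 without ND replicate 1 and 0.0653 without HFD replicate 2, where the median was 0.19. Timp2, an inhibitor of metalloproteinases, rose 2.33-fold from 11.6 ± 1.97 to 27.0 ± 3.91 CPM, and the collagen genes Col1a2 and Col3a1 rose 2.04-fold and 2.03-fold. Markers of stellate cells and fibroblasts, which include Col3a1, had 5 of 16 tested members risen and 2 fallen, 5 and 3 when adjusted over the list alone (median 0.33, camera adjusted p = 0.107). Colec11, a collectin gene, rose by a log2 fold change of 1.02 ± 0.17. After the length and GC correction 4 of these markers were higher and none lower.

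No cell type list passed the list test as counted. Hepatocyte markers had 3 of 15 risen and 2 fallen, 4 and 3 when adjusted over the list alone (camera adjusted p = 0.624), with Tdo2, a tryptophan-degrading enzyme gene, fallen 3.06-fold and Ass1, a urea cycle gene, risen 2.03-fold. The log2 fold change of Tdo2 was -1.61 as counted and -0.73 after the length and GC correction. Pericentral hepatocyte markers had 4 of 12 risen and 2 fallen (median 0.26, mean -0.02, camera adjusted p = 0.715), and periportal markers 3 and 2 of 12 (3 and 3 when adjusted over the list alone, camera adjusted p = 0.608). After the length and GC correction 3 pericentral markers were higher and 1 lower, and 1 periportal marker was higher and 2 lower. Endothelial markers had 4 of 14 risen and none fallen (median 0.43, camera adjusted p = 0.0707), and 1 was higher after the length and GC correction. The 4 were Gpr182, Vwf, Oit3 and Eng, and none of them passed without ND replicate 2 (adjusted p = 0.0654, 0.0677, 0.172 and 0.159) or without HFD replicate 2 (adjusted p = 0.123, 0.180, 0.159 and 0.187). Eng did not pass without HFD replicate 1 either (adjusted p = 0.0556).

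For Kupffer cell markers 1 of 12, Fcna, rose and 1, C6, fell (3 and 1 when adjusted over the list alone, median 0.40, camera adjusted p = 0.537). C6 is also a male-biased member of the list of liver genes that differ between the sexes, most of which fell. For monocytes and recruited macrophages 1 of 10, Fcgr1, rose (none when adjusted over the list alone, camera adjusted p = 0.278), and for dendritic cells 1 of 6, Clec9a, fell (3 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.215). Fcna and Fcgr1 did not pass without ND replicate 2 (adjusted p = 0.154 and 0.102) or HFD replicate 2 (adjusted p = 0.233 and 0.364). Clec9a did not pass without ND replicate 1 (adjusted p = 0.106), HFD replicate 1 (0.0616) or HFD replicate 2 (0.202). None of the 3 passed with the length and GC correction (adjusted p = 0.187, 0.106 and 0.0842), and Fcgr1 and Clec9a did not pass with DESeq2 (adjusted p = 0.156 and 0.117). None of 7 cholangiocyte markers passed (camera adjusted p = 0.318). Of 6 adipocyte markers 2, Cfd and Cidec, rose and Lpl fell (camera adjusted p = 0.107, adjusted p = 0.671 with an estimated correlation, and 0.0357 at the fixed correlation with the length and GC correction, where 3 were higher and 1 lower, and 2 and 2 as counted when adjusted over the list alone). Cfd and Cidec are also in the lipid droplet list. Of 6 erythroid markers 4, all haemoglobin genes, rose (camera adjusted p = 0.0548), and Hbb-bs measured 225 and 204 CPM in ND against 471 and 338 CPM in HFD. Without HFD replicate 1 Hbb-bs did not pass (adjusted p = 0.0648), and with the length and GC correction 2 of the 6 markers were higher. Of 14 cell cycle genes Cdkn1a rose and Ccne1 fell (median -0.04, mean 0.10, camera adjusted p = 0.608), and Ccne1 did not pass without ND replicate 2 (adjusted p = 0.146), HFD replicate 1 (0.0774) or HFD replicate 2 (0.0949).

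The remaining cell type lists had under 5 tested members and no list test. Of the 3 neutrophil markers tested S100a9 fell (log2 fold change -2.95 ± 0.56, and -2.31 without ND replicate 2 and -3.57 without HFD replicate 1), and all 3 were lower when adjusted over the list alone. Of the 3 markers of B and plasma cells Jchain (1.73 ± 0.42) and Sdc1 (0.65 ± 0.18) passed, but the adjusted p of Jchain was 0.0972 without HFD replicate 1 and 0.0648 without HFD replicate 2, and that of Sdc1 0.189 without HFD replicate 2. All 3 were higher when adjusted over the list alone. With the length and GC correction the log2 fold change of Jchain was 2.64, and Sdc1 did not pass (adjusted p = 0.0984). Jchain did not pass with DESeq2 (adjusted p = 0.0571). The single tested marker of T and NK cells, Cd4 (-0.01 ± 0.35), the 2 of pancreatic acinar cells, Cela1 and Cela2a (0.50 ± 0.17 and 0.14 ± 0.30), and the 1 of skeletal muscle, Des (0.30 ± 0.31), did not pass. Cela1 was higher when adjusted over its list alone.

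**Figure D3:**
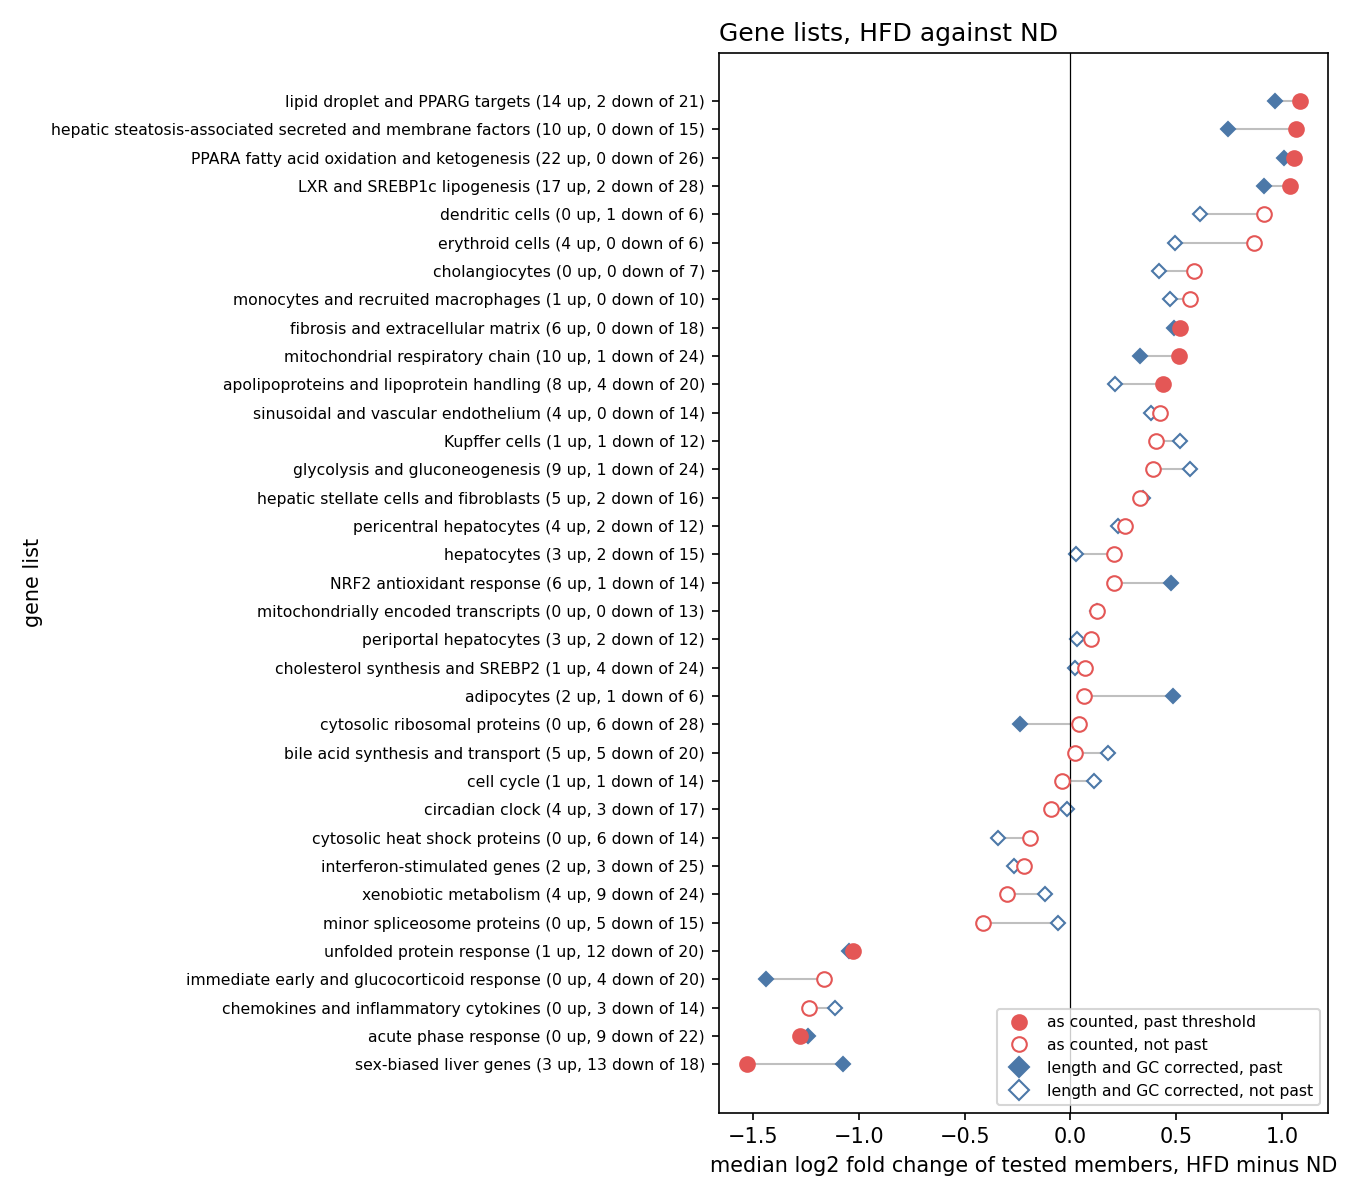
Median log2 fold change (HFD minus ND) of the tested members of 35 gene lists, as counted (circles) and with the length and GC correction (diamonds), filled where the camera adjusted p was under 0.05. Numbers in brackets give the members past the gene test in each direction as counted, such as 22 higher and 0 lower of 26 for fatty acid oxidation.

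The GC content of transcripts was related to the difference between the groups. Genes were put in 10 groups of similar size by GC content. In the group with the lowest GC content (up to 41.5%) the median log2 fold change was -0.99, and 701 of 1186 genes were lower and 27 higher. In the group with the highest GC content 21 of 1185 genes were lower and 235 higher, with a median of 0.35. For each library, the log2 deviation from the gene's mean over the 4 libraries was fitted on GC content and log2 length together. Its slope on GC content was -0.30 and -0.31 per 10 percentage points in the ND libraries and 0.21 and 0.40 in the HFD libraries. These slopes are relative to the mean of the libraries, so their signs show a difference between the groups and not the direction within a group. Across genes, which are not independent replicates, the Spearman correlation of the log2 fold change was 0.540 with GC content and -0.286 with transcript length. The median GC content was 43.3% for the genes that were lower and 53.8% for those that were higher. Of the genes higher as counted, 781 were also higher with the length and GC correction, and of those lower 811 were also lower. The correction left the lists of fatty acid oxidation, lipid droplets, lipogenesis and the unfolded protein response past the list threshold at the fixed correlation of 0.01, with medians of 1.01, 0.97, 0.91 and -1.05. As counted, with an estimated correlation, these lists had an adjusted p of 0.580 for the 3 lipid lists and an adjusted p of 0.751 for the unfolded protein response.

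**Figure D4:**
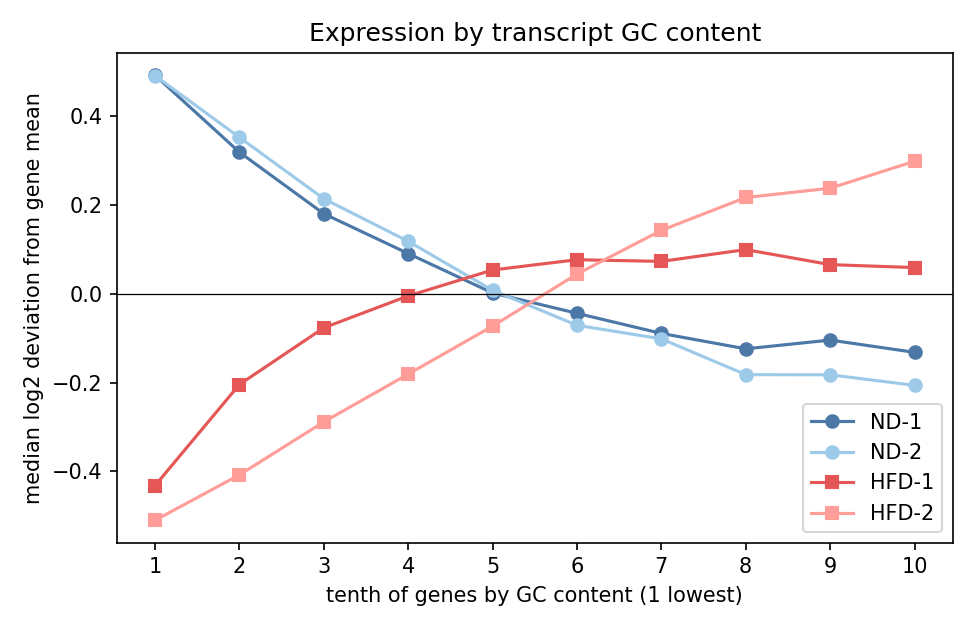
Median log2 deviation of each library from the gene's mean over the 4 libraries (vertical axis), in 10 groups of genes ordered by transcript GC content (horizontal axis). In the lowest group the ND libraries lay at 0.49 and 0.49 and the HFD libraries at -0.43 and -0.51, and in the highest group they lay at -0.13, -0.21, 0.06 and 0.30.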

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

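Chosen after seeing the data were the settings with the length and GC correction and the newer quasi-likelihood method. The 1402 higher and 2273 lower genes became 523 and 1474 at 2-fold or more. Against a fold change of 1.2, 877 were higher. With the length and GC correction 930 were lower, and with that correction without ND replicate 2, 815 were higher and 593 lower. Leaving out 1 library gave 417 to 1779 higher and 1132 to 2567 lower genes, with the lowest counts without HFD replicate 2 and the highest without ND replicate 1. In the fits without an HFD library the spread came from the ND pair alone. That pair differed more than the HFD pair (SD of the log2 difference 0.511 against 0.405). A call lost there can come from the wider spread as well as from the library left out, and which of these lowered the counts was not tested. Both fits took their spread from the same ND pair, so that spread does not explain why their counts differed from each other. Other settings stayed within the ranges from leaving out 1 library or close to them (DESeq2 1141 and 1668, upper quartile factors 1741 and 2107, no filter 1813 and 2742). Upper quartile factors moved the median of all genes by 0.07. The share of higher genes was 38.1% as counted and 57.0% with the correction. The newer quasi-likelihood method gave 1413 and 2276.

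Of the gene lists, 7 were higher and 3 lower. The estimated correlation, which has little power at 2 libraries per group, and fry left 0 higher and 0 lower. With fry the adjusted p of the 10 called lists ran from 0.0803 to 0.433. Lists lower in HFD numbered 5 with the correction and 7 with the correction without ND replicate 2. Leaving out 1 library gave 9 to 11 higher and 4 to 7 lower lists. The calls lost were those given in the report: acute phase genes without ND replicate 2 (but not with the correction without it, adjusted p = 0.00441), fibrosis without ND replicate 1 or HFD replicate 2, and apolipoproteins with the correction and with the correction without ND replicate 2.

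Of 141 genes chosen by the rule 129 were past the threshold. The rule mostly takes genes that pass, so this share was largely set by the choice. The tallies that follow do not carry over to all called genes. With the length and GC correction 108 of the 141 kept direction and call. Of all genes called as counted, that correction kept 55.7% of the higher and 35.7% of the lower ones. Over the 13 settings that followed single genes (not the fold-change thresholds or the correction without ND replicate 2, and 130 of the genes with the stricter filter) 1686 values kept direction and call, 111 lost the call, 14 gained it and 11 reversed. The reversed values included Zrsr2 0.20, Rnpc3 0.30, Chordc1 0.45 and Cela2a -0.21 with the correction, and Cd4 0.0072 with DESeq2 size factors, 0.0570 with upper quartile factors and 0.0059 with DESeq2. Over the fits that left out 1 library, Cd4 ranged from -0.20 to 0.17, Des from -0.0038 to 0.69 and Egr1 from -4.78 to 0.20. Of these Rnpc3, Chordc1 and Egr1 were past the threshold as counted. The cause of these reversals was not tested.

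The groups share replicate numbers, but nothing says that a number marks a shared animal or day, and with 2 pairs the correlation of deviations from the group means was -0.0129. With the replicate number as a block 1486 genes were higher and 2430 lower, and lists lower in HFD numbered 5. Depth limits genes of few counts, such as Cyp2b9 in ND and Moxd1 in HFD.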

Other observations

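All tests of this part were chosen after the results were seen, and so were the genes and families named here.

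Gene families, taken by the stem of the symbol, were scanned for members past the threshold in 1 direction (one-sided hypergeometric test, Benjamini-Hochberg over 365 families of at least 5 tested members). This test takes the members of a family as independent of each other, so its p-values do not measure the spread between libraries. All 24 tested major urinary protein genes were lower in HFD (median log2 fold change -2.88, adjusted p = 5.19e-16), and 19 with the length and GC correction, although these near-identical genes share reads. Aldehyde dehydrogenases, which oxidise lipid aldehydes among other substrates, had 9 of 15 members higher and none lower (median 0.58, adjusted p = 0.00259), and 8 with the correction. Acyl-CoA thioesterases had 6 of 10 higher and none lower (median 0.79, adjusted p = 0.0331), with 6 after the correction as well. Collagen genes had 8 of 20 higher and none lower (median 0.60, adjusted p = 0.0398), and 5 with the correction. Zinc finger genes of the Zfp stem had 85 of 251 members lower and 9 higher (median -0.56, adjusted p = 2.24e-07), but 18 lower and 3 higher with the correction. The other stems past the threshold towards lower were Ugt, Usp and Herc. Ugt had 9 of 13 members lower and 1 higher as counted, and 6 lower and 2 higher with the correction. Usp had 18 of 41 members lower as counted and 4 with the correction, and Herc 5 of 5 and 1, with none higher in either. Towards higher the other stems with no member lower were Ndufb (6 of 10 members higher as counted, 2 with the correction), Dhrs (5 of 8 and 3) and Apoa (4 of 5 and 3). Nudt, Abhd and Tmem also passed towards higher but held members that were lower. As counted Nudt had 8 of 19 higher and 3 lower, Abhd 8 of 20 and 4, and Tmem 31 of 158 and 12. With the correction the counts higher and lower were 2 and 1 for Nudt, 2 and 0 for Abhd, and 16 and 6 for Tmem.

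More genes were lower than higher in HFD, at 61.9% of the changed genes. A difference in library size is argued against by the ratio of mean total counts, HFD to ND, of 1.02. With the length and GC correction 43.0% of the changed genes were lower, so the trend may account for the excess of lower genes. It does not account for the lipid lists, since the median over the members of the fatty acid oxidation and lipid droplet lists was 1.08 before and 0.97 after the correction. Whether the trend itself came from the libraries or from the diet stays open, because it separates the groups.

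Acute phase and immediate early genes stood high in ND replicate 2, with 39 of 42 tested members above ND replicate 1 and a median log2 ratio of 1.33 (quartiles 0.71 and 2.51). The 2 ND libraries had similar trends, with GC slopes of -0.30 and -0.31 per 10 percentage points, and the fitted trends gave no member of these lists a log2 ratio above 0.0237, which argues against GC content and length. Macrophages, monocytes, dendritic cells or red blood cells in the piece are argued against by their 34 tested markers, whose median log2 ratio was -0.58 (quartiles -0.85 and 0.0679). Neutrophils stay open, since their 3 tested markers had a median log2 ratio of 0.70 at low levels (S100a9 at 2.83 and 6.00 CPM), and so do T, NK, B and plasma cells, which had 4 tested markers together. The design names no biological difference between the ND libraries, so none was tested, and how this library differs stays open.

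Genes of the Y chromosome were lower in HFD. Ddx3y, an RNA helicase gene, had a log2 fold change of -2.53 ± 0.24 (SE) as counted and of -1.33 ± 0.22 with the correction (adjusted p = 0.00797). The fitted GC content and transcript length trend between libraries therefore does not account for all of it. That trend is an average over genes, and Ddx3y has a GC content of 36.1%. A larger effect of GC content or length on this gene is not excluded. Eif2s3y (-1.42 ± 0.19 before, -0.34 ± 0.18 after), Kdm5d (-1.21 ± 0.23 and -0.45 ± 0.22) and Uty (-2.04 ± 0.32 and -0.79 ± 0.31) were past the threshold as counted, and 0 of these 3 genes with the correction, whose smaller fold changes ended the calls, so that trend may account for them. A female animal among the HFD libraries is argued against by Xist, a transcript of the inactive X chromosome, with at most 3 counts in any library. Ddx3x, the X-linked relative of Ddx3y, had log2 fold changes of -1.99 ± 0.21 and -1.12 ± 0.20, so the remaining difference in Ddx3y and any effect of the diet on it stay open.

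Male-biased liver genes were mostly lower in HFD, with 13 of 15 tested genes lower and 1, Elovl3, higher, although 6 of the 15 are major urinary protein genes that share reads. Whether livers shifted towards the female pattern stays open, because 3 of the 11 female-biased genes of the list had enough counts to be tested. Of these Cyp2b9 and Hao2 were higher and Cyp2a4 did not pass (log2 fold change 1.07, adjusted p = 0.137). A gene that is silent in ND enters the test only if it rises, so these 3 genes cannot decide it. The other 8 female-biased genes had at most 3 counts in the ND libraries together and at most 14 in the HFD libraries.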
